A study of Mus musculus with 6 samples.

How the data were processed

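Gene expression was measured in intestinal epithelium of 6 mice, 3 labelled Yap control and 3 labelled Yap cKO, all given an adenovirus that carries RSpondin1, a secreted protein that strengthens Wnt signalling. The epithelium was released from the intestine with EDTA, a chelator that loosens epithelial sheets, and total RNA was hybridised to Affymetrix gene arrays, with 1 array per animal. The animals were killed 1 week after the virus. Groups and animal numbers were taken from the sample labels, which name separate mice.

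The values analysed are the deposited log2 signals of 35556 probe sets, and the processing notes of the submitters name Affymetrix Expression Console 1.1 as the tool. The summarization method, the background correction and the annotation version are not given in the sources used here. The values ran from 2.84 to 13.84 with 0 missing values, the medians of the 6 arrays lay between 5.27 and 5.34, and the scale was read as log2 from this range. No further scaling was applied. An array has no read depth, so that 3 animals per group set the precision, and values near the lower end of the range are bounded by background.

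Probe sets were named through the platform annotation, in which 21789 probe sets had 1 gene symbol, 1621 had several and 12146 of the probe sets in the table were not listed. Probe sets with several symbols were given no name. Symbols were compared through Entrez identifiers with a RefSeq gene table of the GRCm38.p6 assembly, and 0 changed. For 999 genes with more than 1 probe set the one with the highest mean over all 6 arrays was kept, which gave 19938 genes. Genes with a mean under the 25th percentile, a log2 value of 4.47, were left out, and 14953 genes were tested. Genes without a named probe set are not analysed here. No build is named for the array annotation, and no coordinates are given.

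Differences between Yap cKO and Yap control were tested two-sided with limma 3.58.1 (lmFit and eBayes, without trend or robust options) in R 4.3.3, with Benjamini-Hochberg adjustment over the 14953 genes and a threshold of 0.05. All log2 changes are cKO minus control, with the moderated standard error (SE). Yap1 was also tested with a two-sided exact permutation test, whose smallest possible p with 3 animals against 3 is 0.1. Gene lists were tested with camera from limma at a preset inter-gene correlation of 0.01, with adjustment over the lists that had at least 4 tested members, and again with an estimated correlation, on ranks and with fry. Adjusted p-values of genes and lists below are from limma unless another test is named. Principal components were taken from the tested genes.

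The 39 gene lists were written from textbook knowledge before the data were examined, as were the tests, the thresholds, the alternatives and the rule for the genes named. They comprise signalling lists (YAP/TAZ targets, Hippo pathway, Wnt targets, Wnt ligands and receptors, EGF family, Notch, BMP and TGF-beta, interferon, p53), epithelial cell types and states, metabolism and stress lists, regional lists of the gut, and markers of other cells the preparation could hold. Overlapping lists are not independent. Some list members have no row in the table used here. The rule named Yap1, Wwtr1, Ccn2 (Ctgf), Ccn1 (Cyr61), Ankrd1, Lgr5, Olfm4, Ascl2, Axin2, Cd44, Sox9, Myc, Lyz1, Muc2, Chga, Alpi, Mki67 and Rspo1 whatever their result. It added the 10 largest rises and falls past the threshold with non-overlapping groups, filled to 5 per direction by smallest p where fewer passed, and from each list up to 4 members past the threshold or, where none passed, up to 2 with the smallest p. Genes without a described symbol (such as predicted genes) and olfactory or vomeronasal receptors were passed over. The rule gave 99 genes. Genes added after their values were seen are said to be so.

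The fit and the list tests were tested on simulated data before use. Of 200 genes changed among 14953 in 20 simulated data sets of 3 against 3 with the residual spread of the real genes, 12.9% were recovered at a log2 change of 0.5, 57.2% at 1 and 85.2% at 2, and 4.88% of the calls were unchanged genes. A list of 30 genes shifted by 0.5 was called in 20 of 20 data sets with either correlation. The simulated noise was independent between genes, while the estimated correlation of the real lists reached 0.87 (MHC class II genes). The changed genes were drawn whatever their spread. In the real data the median residual SD was 0.517 at an absolute log2 change of at least 1 and 0.126 under 0.25. The recovery in the simulation therefore does not carry over to the real genes and lists.

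Alternatives were quantile normalization, equal array medians, an intensity trend with and without robust options, array weights, the animal number as a block, leaving out each animal, no dim filter, a filter at the 50th percentile, the mean over the probe sets of a gene, every probe set without collapse, an adjusted p under 0.1, a test against a fold of 1.2, and the other list tests. A separate test of each Yap1 probe set did not apply, since 1 probe set carried the name. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.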

Results

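Whole intestinal epithelium was profiled from 3 Yap control and 3 Yap cKO mice, 1 week after an RSpondin1 adenovirus. Yap1 encodes the transcriptional co-activator of the Hippo pathway. Every animal had received RSpondin1, so that the comparison addresses which transcripts differed with the Yap genotype under this treatment and holds no untreated animal. The first principal component held 63.8% of the variance. The controls lay at -22.4, -40.6 and -26.0 on it and the cKO animals 1, 2 and 3 at 50.5, 44.7 and -6.23, so that cKO animal 3 lay nearer to the controls than to the other cKO animals.

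Yap1 itself was 8.57-fold lower in the cKO epithelium. Its log2 level was 8.77 ± 0.14 (SD, n = 3) in controls and 5.67 ± 0.09 (SD, n = 3) in cKO animals, a change of -3.10 ± 0.11 (SE; 95% confidence interval -3.36 to -2.84; adjusted p = 0.00168). The 3 control values were 8.64, 8.92 and 8.75, and the 3 cKO values 5.67, 5.58 and 5.76, all below every control. The exact permutation test gave p = 0.1, the smallest that 3 against 3 allows. Yap1 was measured by 1 probe set, identifier 10590808, and which exons it covers in relation to the deleted part is not known here. Without control animal 3 the change was -3.11 and the adjusted p 0.0507, which did not pass.

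Of the YAP/TAZ target genes, 19 of 22 tested members had lower values in the cKO epithelium and 3 had higher values, and the list was called lower (median log2 change -0.15, mean -0.31, adjusted p = 0.00147). The adjusted p = 0.517 with an estimated correlation, which does not pass. Over all genes 0 members passed, and adjusted over the list alone 4 were lower and 2 higher. Wwc1, which encodes the Hippo regulator KIBRA, changed by -1.03 ± 0.12 (SE; adjusted p = 0.0620 over all genes), from 8.46 in controls. Crim1, a transmembrane regulator of BMP signalling, changed by -1.21 ± 0.28 (SE; adjusted p = 0.0719). Nuak2, Amotl2 and F3, added after their values were seen, differed by -1.11, -0.95 and 1.63, and F3, the gene of tissue factor, thus lay opposite to the list. Of the targets most often used as YAP readouts, Ccn1 (Cyr61) differed by -1.06 ± 0.35 (SE; adjusted p = 0.122), Ccn2 (Ctgf) by -0.0013 ± 0.14 (adjusted p = 0.997) and Ankrd1 by -0.13 ± 0.083 (adjusted p = 0.344). Ankrd1 lay at 4.55 in controls, close to the dim filter. Rbms3, Axl and Arhgef17, added after their values were seen, lay at 4.68, 4.86 and 5.16 in controls and each differed by -0.15. Of all tested genes with a control mean under 6, 62.8% were lower. Such dim members of the 19 are not told apart from a small shift of dim probe sets. Wwtr1, which encodes the paralog TAZ, was higher by 0.39 ± 0.14 (SE; adjusted p = 0.138), with its 3 cKO values above every control value. The median of the list was -0.27 without cKO animal 3 and -0.79 with the stricter dim filter, and it was called in both. The sign of Ccn2 turned with array medians set equal.

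**Figure D1:**
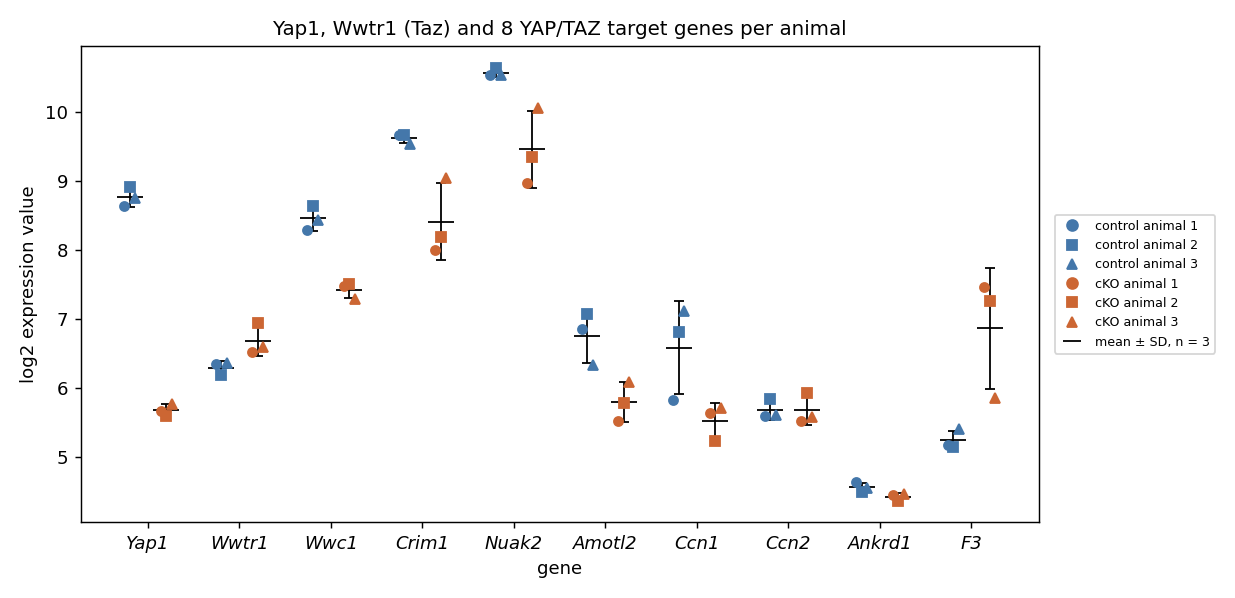
Log2 expression value (vertical axis) of Yap1, Wwtr1 and 8 YAP/TAZ target genes (horizontal axis) in each of the 3 Yap control and 3 Yap cKO animals, with the mean and SD as black bars. The Yap1 values of the cKO animals lie between 5.58 and 5.76, below all controls, while the Ccn2 values overlap.

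Yap1 was the only gene of 14953 past the threshold, so that 1 gene was lower and 0 were higher in the cKO epithelium. At an unadjusted p under 0.05 there were 4154 genes, 2762 higher and 1392 lower, which is 27.8% of the genes tested against 5% by chance. The 3 cKO values lay entirely on 1 side of the 3 control values in 5081 genes, 34.0% against 10% by chance. The next smallest adjusted p was 0.0620, shared by 226 genes. Of those closest to passing, the rises were of Mt1 (1.84 ± 0.14, SE), a metal-binding metallothionein, Slit2 (1.85 ± 0.18), a secreted guidance ligand, Pxylp1 (1.55 ± 0.15), Pcca (0.99 ± 0.091), a subunit of propionyl-CoA carboxylase, and Mrpl50 (0.79 ± 0.075), a mitochondrial ribosomal protein. The falls were of Hs3st1 (-1.27 ± 0.14), a heparan sulfate sulfotransferase, Myo7a (-1.25 ± 0.12), an unconventional myosin, Arhgap45 (-1.19 ± 0.13) and Hes2 (-0.84 ± 0.099). These 9 genes had an adjusted p of 0.0620 and did not pass, although their groups did not overlap. At a threshold of 0.1, 2120 genes passed, 1530 higher and 590 lower (72.2% higher), and after quantile normalization 1455 did, with 57.1% higher. Without cKO animal 3, 3517 genes passed at 0.05, 2082 higher and 1435 lower, and with array weights, which gave that animal a weight of 0.33, 3908 did.

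Of 37 gene lists with enough members, 16 were called, 4 higher and 12 lower in the cKO epithelium, and with an estimated correlation 0 were called (smallest adjusted p = 0.517). By fry in its directional form 0 lists passed (smallest adjusted p = 0.0999), and in its mixed form, which counts change in either direction, 21 did. Single members are described below by values, since none but Yap1 passed over all genes.

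Genes of cell division and of ribosome assembly were higher. All 36 tested cell cycle genes had higher means in the cKO epithelium, with a median log2 change of 1.03 (adjusted p = 1.49e-10, and adjusted p = 0.517 with an estimated correlation). Adjusted over the list alone 25 of them were higher, and over all genes 0 passed. Cenpa, which encodes the centromeric histone, differed by 1.18 ± 0.19 (SE), Ccnb2, a mitotic cyclin, by 1.13 ± 0.25, and the proliferation antigen gene Mki67 by 0.99 ± 0.41 (adjusted p = 0.184; 0.63 to 1.36 with 1 animal left out). The 26 ribosome biogenesis genes had a median of 1.15 (adjusted p = 4.42e-09, and adjusted p = 0.517 with an estimated correlation). Adjusted over the list alone 22 of the 26 were higher. Pes1 differed by 1.08 ± 0.15 and Wdr12 by 1.59 ± 0.30, both encoding parts of the complex that processes large-subunit ribosomal RNA. Myc, which encodes a regulator of ribosome production, was higher by 1.65 ± 0.46 (adjusted p = 0.0949). The mean shift from the control mean was 1.40, 1.19 and 0.39 for cell cycle genes in cKO animals 1, 2 and 3, against -0.0022, -0.35 and 0.35 in the controls. For ribosome biogenesis it was 1.502, 1.128 and 0.557.

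Transcripts of intraepithelial lymphocytes and of antigen presentation were lower. All 20 tested T and intraepithelial lymphocyte markers had lower means, with a median of -1.39 (adjusted p = 3.45e-11, and adjusted p = 0.517 with an estimated correlation), and 19 passed adjusted over the list alone. Cd7, a surface receptor of T cells, differed by -1.48 ± 0.21 (SE) and Cd3d, a chain of the T cell receptor complex, lay at 6.35 ± 0.18 (SD, n = 3) in controls and 5.35 ± 0.33 in cKO animals. The mean shift of the list was -1.77, -1.71 and -0.74 in cKO animals 1, 2 and 3. All 6 MHC class II genes were lower adjusted over the list alone (median -2.57, adjusted p = 2.2e-05, and adjusted p = 0.517 with an estimated correlation). Cd74, the invariant chain, differed by -2.20 ± 0.34 and Ciita, the class II transactivator, by -2.21 ± 0.39. Interferon-stimulated genes had lower means in 28 of 34 members (median -0.61, adjusted p = 1.52e-05, and adjusted p = 0.517 with an estimated correlation), with 3 lower adjusted over the list alone. Parp14 differed by -1.34 ± 0.26 and Psmb8, a subunit of the immunoproteasome, by -1.37 ± 0.29. The interferon list stayed called with medians of -0.40 without control animal 1 or 2 and -0.36 with array weights. Of the myeloid markers 16 of 19 had lower means (median -0.20, adjusted p = 0.00611, and adjusted p = 0.517 with an estimated correlation), and 3 were lower adjusted over the list alone, including Tyrobp (-1.93 ± 0.32) and Ly86 (-0.98 ± 0.16). The myeloid call was lost with the stricter dim filter (median -0.74, adjusted p = 0.316), and without control animal 1 the median was -0.098 (adjusted p = 0.0475). B and plasma cell markers were not called (median -0.21, adjusted p = 0.0555), and Cd79b and Pax5 differed by -0.73 and -0.25. They were called lower without cKO animal 2 (adjusted p = 0.0172), without the dim filter (0.0233) and on ranks (0.0425), while the adjusted p was 0.231 without cKO animal 3 and 0.163 with the stricter dim filter (median -0.47). The B and plasma cell median was -0.13 without control animal 2.

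**Figure D2:**
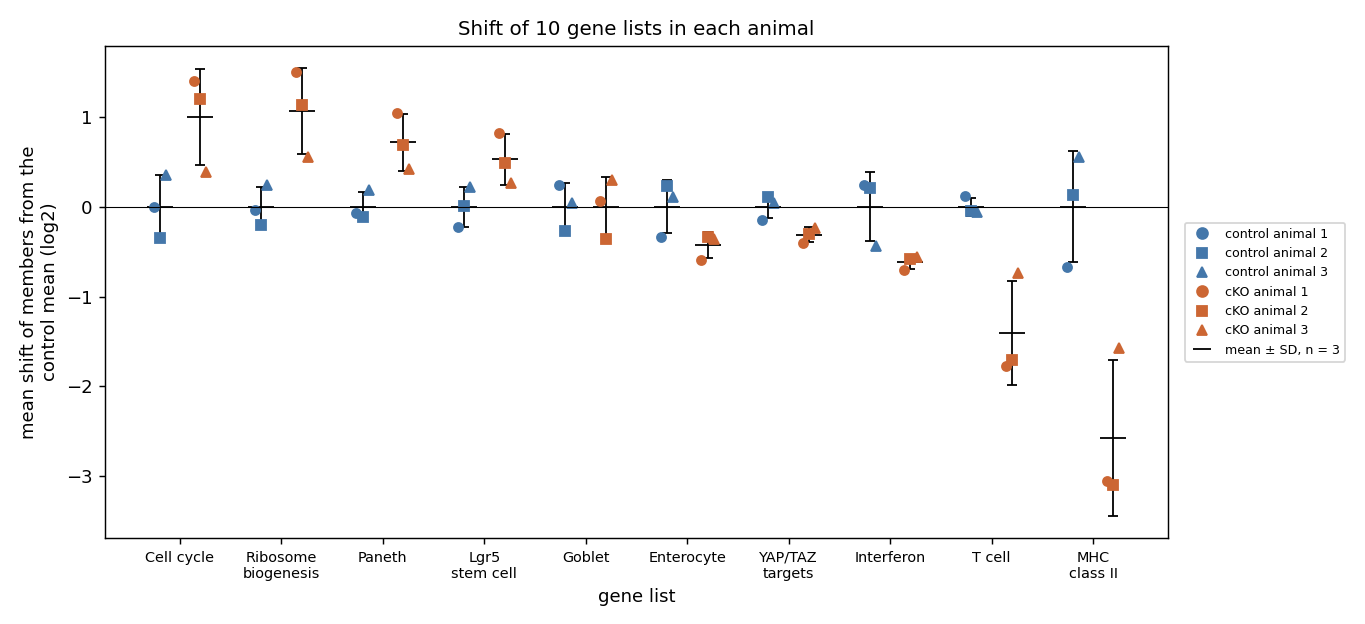
Mean log2 shift of the members of 10 gene lists from the mean of the controls (vertical axis) in each animal, with the group mean and SD as black bars. MHC class II genes lie at -3.05, -3.10 and -1.58 in cKO animals 1, 2 and 3, and the goblet cell values of both groups overlap.

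Markers of crypt cells were called higher as lists, with values that overlapped for several of the best known members. The 34 markers of Lgr5 stem cells had a median of 0.64 (adjusted p = 0.00834, and adjusted p = 0.613 with an estimated correlation), and adjusted over the list alone 1 was higher and 1 lower. The higher member was Nfia (0.73 ± 0.11, SE) and the lower one Cd74, which also belongs to the MHC class II list. Lgr5, a receptor of R-spondins, differed by 0.66 ± 0.35 (adjusted p = 0.275), Olfm4 by 0.62 ± 0.38 (adjusted p = 0.339) and Ascl2 lay at 6.94 ± 0.59 (SD, n = 3) in controls and 8.14 ± 0.77 in cKO animals (adjusted p = 0.161). Lgr5 differed by 0.29 without cKO animal 1 and by 1.015 without cKO animal 3, where it passed (adjusted p = 0.0357), and Olfm4 by 0.26 without cKO animal 1 and 0.38 without control animal 2. The stem cell list was not called without cKO animal 1 (median 0.36, adjusted p = 0.0623) or with the stricter dim filter (0.113). Wnt/beta-catenin targets were not called (median 0.30, adjusted p = 0.0808), but were without cKO animal 3 (adjusted p = 0.00694), without control animal 2 (0.0438), with array weights (0.0486), without the dim filter (0.0426) and with the stricter one (0.0308). The Wnt target median was 0.13 without control animal 1 (adjusted p = 0.403) and 0.15 without cKO animal 1 (0.384). Cd44, a hyaluronan receptor, was higher by 1.78 ± 0.38 and Slc12a2, an ion cotransporter, by 1.65 ± 0.41, while Sox9 differed by 0.58 ± 0.45 and Axin2, the feedback inhibitor of Wnt signalling, by -0.43 ± 0.26 (adjusted p = 0.339). Sox9 differed by 0.099 without control animal 1 and 0.93 without control animal 2, and Axin2 by -0.25 without cKO animal 2 and -0.26 without control animal 2. Stem cell and Wnt genes may have been examined by the study itself on these samples. All 15 tested Paneth cell markers had higher means (median 0.58, adjusted p = 0.00288, and adjusted p = 0.517 with an estimated correlation), and 0 passed adjusted over the list alone. The Paneth list held 30 symbols, of which only 16 were measured here. Lyz1, Paneth cell lysozyme, differed by 0.58 ± 0.24 (0.31 to 0.75 with 1 animal left out), Wnt3 by 0.94 ± 0.26 and Tnfaip8l1 by 0.61 ± 0.18.

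Absorptive enterocyte markers were called lower as a list. Of 30 members 27 had lower means (median -0.35, adjusted p = 7.85e-07, and adjusted p = 0.517 with an estimated correlation), and 6 were lower adjusted over the list alone. Dpp4, a brush border peptidase, differed by -0.69 ± 0.097 (SE) and Apob, the apolipoprotein of chylomicrons, by -0.64 ± 0.093. Alpi, intestinal alkaline phosphatase, differed by -0.30 ± 0.11 (adjusted p = 0.142). The mean shift of the list was -0.59, -0.34 and -0.36 in cKO animals 1, 2 and 3 and -0.34 in control animal 1. Proximal small intestine genes were called lower (median -0.25, adjusted p = 0.0359, and adjusted p = 0.517 with an estimated correlation), with 3 of 15 lower adjusted over the list alone. The proximal median was -0.11 without cKO animal 1 and -0.40 without cKO animal 3, and the list was called in both. Heph, a copper-dependent ferroxidase, differed by -0.72 ± 0.13 and Adh6a by -1.16 ± 0.27. Ileum genes were called lower (median -0.64, adjusted p = 0.0491, and adjusted p = 0.517 with an estimated correlation), with 3 of 11 lower adjusted over the list alone, among them the metalloprotease gene Mep1b (-0.89 ± 0.17) and the bile acid transporter gene Slc51a (-0.93 ± 0.20). The members Fabp6 and Slc10a2, added after their values were seen, were left out by the dim filter. They lay at 4.15 to 4.72 and 4.04 to 4.99 in controls. Mep1b is also in the enterocyte list, so that a loss of ileal expression is not shown. The ileum call was lost without control animal 3 (median -0.32, adjusted p = 0.105), without cKO animal 3 (0.248), with array weights (0.0887) and on ranks (0.0561), and without the dim filter the median was -0.34. Colon genes were not called (median -0.14, adjusted p = 0.151), with medians of -0.50 with the stricter dim filter and -0.076 with array weights. Mettl7b and Car4, a carbonic anhydrase, differed by -3.06 ± 0.81 and -1.83 ± 0.60.

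Secretory lists other than the Paneth list moved little or varied widely. Goblet cell markers had a median of -0.028 (adjusted p = 0.942), which was -0.20 without control animal 2 and 0.20 without cKO animal 2. Muc2, the main intestinal mucin, differed by -0.30 ± 0.27 (SE; adjusted p = 0.515; -0.50 to -0.067 with 1 animal left out), while the chemokine Ccl9 (1.88 ± 0.30) and Galnt12 (0.98 ± 0.21), a glycosyltransferase, were the 2 members higher adjusted over the list alone. Enteroendocrine markers had a median of 0.13 (adjusted p = 0.0758). Neurog3 and Neurod1, transcription factors of endocrine progenitors, differed by 1.13 ± 0.24 and 0.82 ± 0.19, and Chga by 0.45 ± 0.18 (adjusted p = 0.168). The enteroendocrine list was called without control animal 1 (median 0.27, adjusted p = 0.00443), cKO animal 1 (0.21, 0.0165), cKO animal 2 (0.17, 0.0311) or the dim filter (0.0233). Its median was 0.036 without cKO animal 3 (adjusted p = 0.549) and 0.28 with the stricter dim filter (0.230). Tuft cell markers were called lower (median -0.39, adjusted p = 0.0392, and adjusted p = 0.755 with an estimated correlation), with 0 of 18 lower adjusted over the list alone, and Plcb2 and Vav1 differed by -0.95 and -0.69 (-1.25 to -0.59 and -0.92 to -0.37 with 1 animal left out). The mean shift of the tuft cell list was -0.57, 0.87 and -0.30 in the controls. Without control animal 2 the median was 0.065 and the adjusted p 0.473, and without cKO animal 1 or 2 the adjusted p was 0.136 (median -0.20) or 0.0727. Quantile normalization also ended the tuft cell call (0.0512), while the medians were -0.74 without control animal 1 and -0.84 without cKO animal 3.

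**Figure D3:**
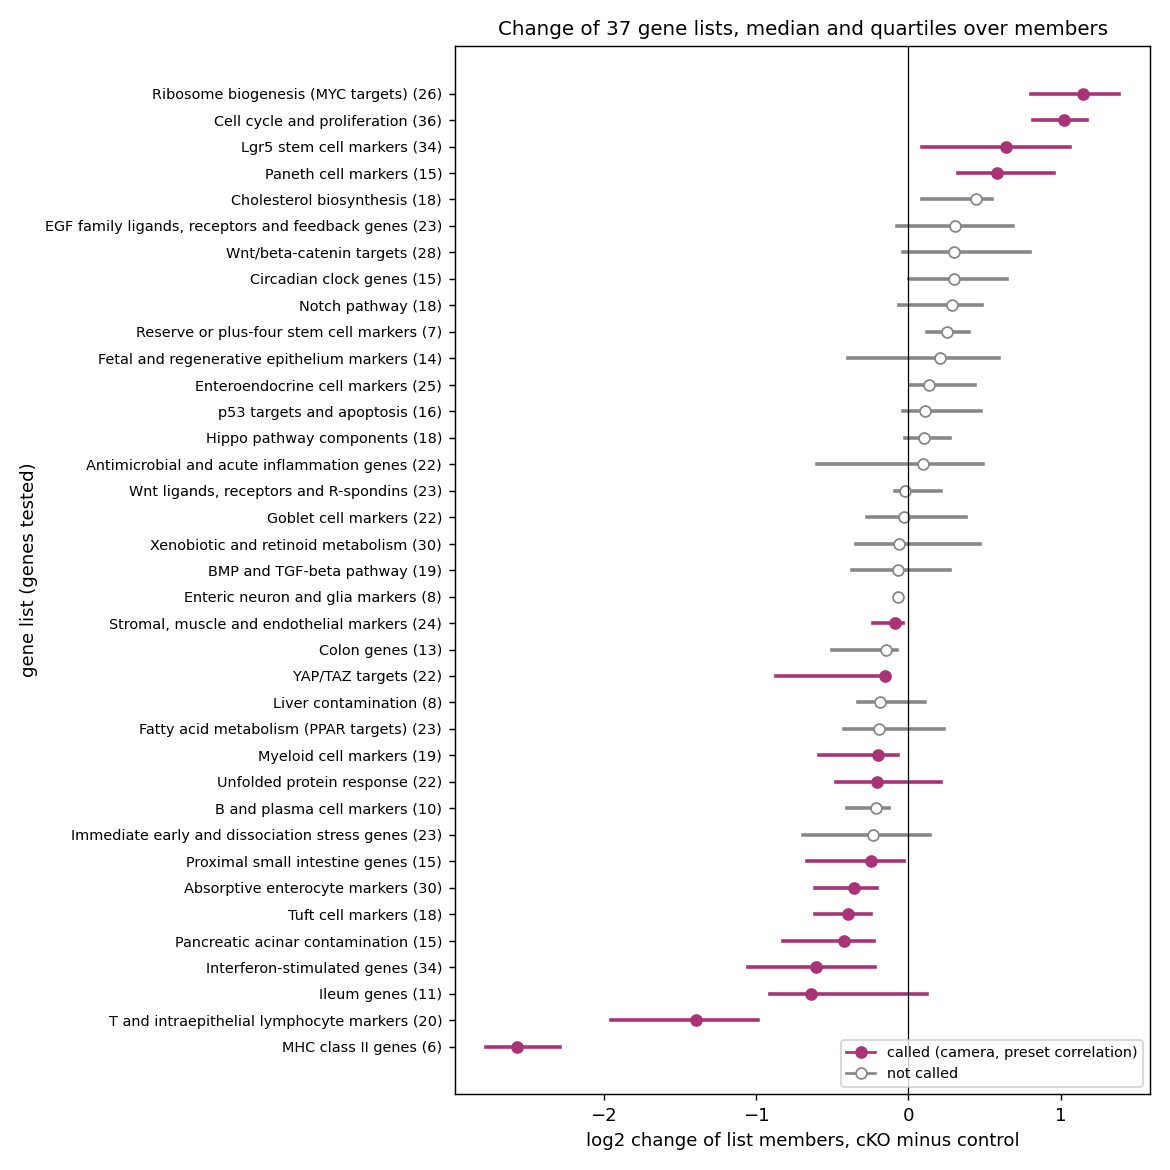
Median (point) and quartiles (bar) of the log2 change, cKO minus control, over the tested members of 37 gene lists, with the number of members beside each name and filled points for lists called by camera with the preset correlation. Medians run from -2.57 for MHC class II genes to 1.15 for ribosome biogenesis.

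Lists of tissue outside the epithelium had medians below 0, and some of their members were higher. Not all members were dim, since Cps1, Rnase1 and Zg16 lay at 11.73, 10.42 and 12.73 in controls. Stromal, muscle and endothelial markers were called lower (median -0.087, adjusted p = 0.0207, and adjusted p = 0.517 with an estimated correlation), with 0 of 24 lower adjusted over the list alone, among them Tek, an endothelial receptor (-1.32 ± 0.37, SE), and Myh11 (-0.24 ± 0.079). The call was lost without control animal 1 (adjusted p = 0.0947) or cKO animal 1 (0.0531), after quantile normalization (0.0761), with array weights (0.0659) and with the stricter dim filter (0.170). Pancreatic acinar genes were called lower (median -0.42, adjusted p = 0.0392, and adjusted p = 0.698 with an estimated correlation), with 0 of 15 past the list alone. Rnase1 lay opposite to the list at 0.95 ± 0.30 and Zg16, also a goblet cell gene, at -0.28 ± 0.13. That call held in 2 of the 6 fits without 1 animal and was lost without control animal 2 (adjusted p = 0.0866), control animal 3 (0.150), cKO animal 2 (0.0727) or cKO animal 3 (0.103), as well as after quantile normalization (0.0512), without the dim filter (0.0515) and with the stricter one (0.160). The pancreatic median was -0.28 without control animal 2, -0.27 without control animal 3, -0.72 without control animal 1 and -0.71 with array weights. Enteric neuron and glia markers (median -0.067, adjusted p = 0.354; Sox10 -0.16 and Uchl1 -0.10) and liver genes (median -0.19, adjusted p = 0.675) were not called, with medians of -0.013 and -0.056 without control animal 1. Ttr, the transthyretin gene, was the liver list's 1 member higher adjusted over the list alone (1.68 ± 0.33), and Cps1 differed by 0.49. Whether the Ttr and Cps1 signals came from liver or from the epithelium was not tested. Erythroid and sex-linked lists had too few tested members for the list test. Alas2, the erythroid enzyme of haem synthesis, differed by -1.33 ± 0.28 and Slc4a1 by -0.26, and Xist lay between 10.05 and 11.42 in all 6 animals.

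Unfolded protein response genes were called lower (median -0.20, adjusted p = 0.0430, and adjusted p = 0.698 with an estimated correlation), with 0 of 22 past the list alone. Asns, asparagine synthetase, lay at 1.52 ± 0.41 (SE), opposite to the list, and Creld2 at -0.57 ± 0.17. The call was lost without control animal 2 (adjusted p = 0.0564), control animal 3 (0.0847), cKO animal 2 (0.108, median -0.11) or cKO animal 3 (0.103), with the animal number as a block (0.0647) and without the dim filter (0.0595). The median was -0.31 without control animal 1 and -0.33 with array weights. Immediate early genes (median -0.23, adjusted p = 0.0825) and p53 targets (median 0.11, 0.033 to 0.22 with 1 animal left out, adjusted p = 0.486) were not called. Dnajb1 and Ier2 differed by -0.66 and 0.62, and Aen and Gtse1 by 0.61 and 0.88.

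The remaining signalling lists were not called. Medians were 0.11 for Hippo pathway components (adjusted p = 0.605), where only Yap1 passed, 0.29 for the Notch pathway (adjusted p = 0.266), 0.31 for EGF family genes (adjusted p = 0.189), -0.065 for BMP and TGF-beta genes (adjusted p = 0.831) and -0.024 for Wnt ligands and receptors (adjusted p = 0.872). With 1 animal left out they ran from 0.099 to 0.19 for Hippo, -0.12 to -0.031 for BMP and TGF-beta, and -0.041 to 0.0048 for Wnt ligand genes. After quantile normalization the medians were 0.184 for Notch and 0.062 for Hippo, and with array weights the Notch median was 0.175. Notch2 and Rbpj differed by 1.11 ± 0.25 (SE) and 0.44 ± 0.11. In the EGF list the phosphatase genes Dusp4 and Dusp6, both feedback regulators of MAP kinases, went opposite ways, at 1.43 ± 0.32 and -1.18 ± 0.22, and Dusp6 was the 1 member lower adjusted over the list alone. Ptch1, the hedgehog receptor, and Tgfbr1 were the 2 members of the BMP and TGF-beta list higher adjusted over the list alone, at 0.77 ± 0.12 and 0.68 ± 0.14. Fzd6 differed by 0.97 ± 0.23, and endogenous Rspo1 by -0.13 ± 0.089 (adjusted p = 0.373).

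Metabolic, regenerative and inflammatory lists were not called either. Medians were 0.45 for cholesterol synthesis (adjusted p = 0.131), -0.19 for fatty acid metabolism (adjusted p = 0.285), -0.063 for xenobiotic metabolism (adjusted p = 0.736) and 0.30 for clock genes (adjusted p = 0.368). They were 0.21 for fetal and regenerative markers (adjusted p = 0.912), 0.25 for reserve stem cell markers (adjusted p = 0.230) and 0.099 for antimicrobial and inflammation genes (adjusted p = 0.564). Without control animal 1 the cholesterol (adjusted p = 0.00254), fatty acid (0.0279), xenobiotic (0.000107) and immediate early (0.0202) lists were called. The cholesterol list was also called without the dim filter (0.0494) and the immediate early list with the stricter one (0.0256). Without control animal 2 the medians were 0.15 for cholesterol (adjusted p = 0.695), -0.0058 for fatty acid (0.645) and 0.33 for xenobiotic genes (0.433), and the latter were also above 0 without control animal 3 (0.16) or cKO animal 1 (0.079). The fatty acid median was 0.013 without cKO animal 1. With 1 animal left out the medians ran from 0.045 to 0.51 for clock genes, -0.055 to 0.14 for antimicrobial genes, 0.094 to 0.37 for fetal and 0.13 to 0.42 for reserve stem cell markers, and none of these lists was called. Duox2 (-1.85 ± 0.34, SE) and Duoxa2 (-1.65 ± 0.32), the epithelial oxidase and its maturation factor, were among the 3 inflammation genes lower adjusted over the list alone, and the alarmin Il33 (-2.44 ± 0.51) was the 1 such member of the fetal list, where Basp1 differed by -0.51. Sult1b1 (-1.08 ± 0.18) was the 1 xenobiotic gene lower adjusted over the list alone, while Akr1b8, an aldo-keto reductase, lay at 2.36 ± 0.54. Mvk, mevalonate kinase (0.53 ± 0.11), was the 1 cholesterol gene higher adjusted over the list alone, and Lss differed by 0.95 (0.57 to 1.27 with 1 animal left out). Bmi1 and Lrig1 differed by 0.49 and 1.23, Ppargc1a and Fabp1 by -0.68 and -0.25, and Arntl and Per1 by -0.81 and 1.87. Per1 lay at 5.99, 6.09 and 7.27 in controls and 8.73, 9.31 and 6.94 in cKO animals 1, 2 and 3. Arntl lay at 8.49, 7.897 and 7.75 in controls and 7.03, 7.05 and 7.64 in the cKO animals. Ciart, added after its values were seen, differed by 1.79, with 7.32, 7.93 and 4.76 in the cKO animals. The mean shift of the clock list was 0.390, 0.795 and 0.0720 there, against -0.317, 0.0996 and 0.218 in controls. In 7 lists, none of them called, the median, the mean and the test differed in sign (antimicrobial, Hippo, liver, xenobiotic, Wnt ligands, fetal and goblet).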

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

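The gene count moved with the settings and with the animal left out. With an intensity trend 2 genes passed (Yap1 and Mt1), with array weights 3908, with an adjusted p under 0.1 2120, and leaving out 1 animal gave 0 (without control animal 3) to 3517 (without cKO animal 3). The cause was not tested, except that median residual SD was 0.517 in the 954 genes with an absolute log2 change of at least 1 and 0.126 in the 8247 genes under 0.25. In the former the median SD was 0.316 among controls and 0.595 among cKO animals. Yap1 stayed lower in every fit, from -3.15 to -3.09 in 8 other settings and from -3.17 to -3.02 without 1 animal (adjusted p 0.00372 to 0.0507). Of the 8 settings only quantile normalization, equal array medians and array weights could move its change. The trend options, the dim filters and the mean over probe sets leave the values of its 1 probe set as they are. Called lists numbered 13 to 20 without 1 animal, 0 with an estimated correlation and 0 by directional fry. Of 606 values of lists under the other settings, 559 kept their side of the threshold, 29 lost and 18 gained a call. The intensity trend, with and without robust options, does not enter the list test. The 37 list values in each of these settings could not move and are among the 559. Of 1457 values of named genes, 145 gained a call, nearly all with array weights (75) or without cKO animal 3 (69). Ccn2, near 0, turned sign with equal array medians (0.0060), with array weights (0.088) and in fits without 1 animal (-0.13 to 0.077). Signal near background limits Ankrd1 and most stromal, neuronal, myeloid and B cell markers.

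With the animal number as a replicate block 0 genes passed and Yap1, at -3.10, had an adjusted p of 0.145. The block leaves fewer degrees of freedom, and whether this alone raised the adjusted p was not tested. The lists called numbered 15. Animals of the same number correlated at 0.24, -0.018 and -0.014 in their deviations from the group means, and 2 of the 6 (control 1 and cKO 1) correlated best with their own number. The values thus show no clear pairing, but with so few animals they cannot exclude a shared litter or day, which the labels do not give.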

Other observations

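Tests of the explanations below were chosen after the results were seen, apart from the 10 glucocorticoid-induced genes not looked at before and the splits of the animals. Beyond the lists, gene families that share the opening letters of their symbols were scanned with camera, a scan also chosen after the values were seen. Of 183 families with at least 10 tested genes, 27 were called higher and 7 lower with the preset correlation, and 0 with an estimated correlation (smallest adjusted p = 0.600). Ribosomal protein genes of the large subunit (Rpl) had higher means in 33 of 34 members (median 0.56, adjusted p = 5.31e-09) and of the small subunit (Rps) in 26 of 30 (median 0.52). Nucleoporin genes (Nup) were higher in 19 of 19 members (median 0.70), Mcm genes of the replicative helicase family in 10 of 10 (0.98), RNA polymerase genes (Polr) in 25 of 27 (0.55), and mitochondrial ribosomal genes (Mrpl) in 39 of 48 (0.24). Collagen genes (Col) were lower in 43 of 44 members, with a median of -0.14 at a median control level of 5.56. Other dim families were called lower by similar amounts, among them keratin-associated proteins (Krtap, 18 of 18 lower, -0.11) and microRNA genes (Mir, 82 of 110, -0.088), and 62.8% of the 5288 tested genes with a control mean under 6 were lower (median -0.042), so that the collagen values are not told apart from a small shift of dim probe sets. The signs of the families named were the same after quantile normalization and with equal array medians.

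In 24 genes, chosen after their values were seen, the 3 cKO and the 3 control values were parted by a gap of more than 1 on the log2 scale, 13 higher and 11 lower, and only Yap1 of them passed. Genes without a described symbol and olfactory or vomeronasal receptors were left out of this count. Nlrp1b, an inflammasome sensor, lay at 6.20, 8.30 and 7.99 in controls and at 4.56, 4.68 and 4.53 in cKO animals, and passed besides Yap1 without control animal 1 (adjusted p = 0.00977). Sema3c, a secreted semaphorin, lay 5.98-fold higher (2.58 ± 0.33, SE), the stress gene Ddit4 4.35-fold higher (2.12 ± 0.32), and Hsd11b2, the enzyme that inactivates glucocorticoids, 3.59-fold higher (1.84 ± 0.36). Susd2 lay 11.7-fold lower (-3.54 ± 0.74) and Il2rb, a receptor chain of lymphocytes, 3.54-fold lower (-1.82 ± 0.25). Among the 12 genes on each side of Yap1, 6 were tested and 0 passed (limma; smallest adjusted p = 0.115). Since only Yap1 passed among all genes, this count tells little. The groups did not overlap in Mmp7, Mmp20, Tmem123 and Birc2 (1.46, 0.25, 0.53 and -0.37), but did in Birc3 and Arhgap42 (0.0035 and -0.85). Of all tested genes 34.0% had no overlap. Mmp7 is also in the Paneth cell and Wnt target lists. Several absorptive genes varied within groups. Lct, the lactase gene, lay at 12.02, 12.76 and 12.57 in controls and 8.47, 9.10 and 12.07 in cKO animals, and Cyp2c29 at 4.79, 11.26 and 9.92 against 4.63, 4.55 and 7.33.

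The position of cKO animal 3 near the controls on the first principal component was set against 3 explanations. A difference in the time of day of killing was not among them and was not tested. Per1, a clock gene with values given above, is also among the 13 glucocorticoid-induced genes seen before. A wrong genotype label would need Yap1 at a control level, but it was 5.76 in that animal, below the lowest control value of 8.64. Control RNA mixed into the sample would, at the shares that fit the other genes best (72% with cKO animal 1 and 73% with animal 2), put Yap1 at 8.36 or 8.37, far above 5.76. A glucocorticoid-type response was raised by 13 genes seen before, all higher in cKO animals 1 and 2 (median shifts 1.90, 2.30 and 0.47 in cKO animals 1, 2 and 3, with Ddit4, Mt1, Klf9 and Glul above every control in animal 3 too), among them Fkbp5, at 6.77, 7.54 and 6.34 in controls and 10.81, 11.18 and 6.71 in cKO animals, and Zbtb16, at 5.65, 5.27 and 5.22 against 8.85, 9.74 and 5.10, while 10 other genes of this kind had median shifts of -0.094, 0.035 and -0.011 in cKO animals 1, 2 and 3, and of these Rasd1 had the same pattern (7.13, 5.14 and 5.22 against 9.53, 9.74 and 5.38). The medians lay at percentiles 29.0, 62.8 and 22.1 of 10000 random lists matched on level, and a percentile under 50 in animal 1 or 2 had been set beforehand as evidence against this response, but a bootstrap interval added after that result was seen (-0.63 to 0.032 in animal 1) held the median of the random lists (-0.021), so that the response stays open without support from the genes written in advance.

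The lower T cell and MHC class II genes were not removed by other scaling, since the T cell list had medians of -1.46 after quantile normalization and -1.38 with equal array medians. These rescalings moved the median change of all genes by only -0.013 and 0.0073. They could not test the summarization or background correction by the authors. A lower yield of leukocytes of every kind could contribute and cannot be told apart from a loss of T cells. Only 5 B cell and myeloid markers had a control mean above 7, with a median change of -0.45 and quartiles of -1.93 and -0.23. Fcer1g (-1.96) and Tyrobp (-1.93), which lymphocytes also express, lay low, and Lyz2 (0.66) lay high, as did Lyz1, Paneth cell lysozyme (0.58). Which cells gave the Lyz2 signal was not tested. The Yap genotype stays among the open explanations.

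The higher cell cycle and ribosome biogenesis genes beside lower enterocyte markers kept medians of at least 0.94 after both rescalings. As above, the rescalings moved the values little and could not test the summarization or background correction by the authors. A lower share of absorptive enterocytes alone would raise markers of every other cell type, but all 20 T cell markers had lower means. This argues against it as the whole cause. The cell cycle shift exceeded the T cell shift by 2.40 on average (3.17, 2.90 and 1.13 in cKO animals 1, 2 and 3 against -0.12, -0.30 and 0.41 in the controls). That difference follows from the list results above and is no separate evidence. A lower share beside a separate loss of lymphocytes could contribute. The cell cycle shift exceeded the goblet cell shift by 1.00 on average, but the values of 1.34, 1.56 and 0.099 in cKO animals 1, 2 and 3 overlapped with -0.24, -0.071 and 0.31 in the controls. This explanation and an effect of the Yap genotype stay open.

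The 6 animals allow 10 splits into groups of 3, too few for a share under 0.05. The real split gave 1 gene and the highest other split 7, so that 2 splits gave at least as many. That split, of control animal 1 with cKO animals 1 and 2 against the rest, still sets cKO animals 1 and 2 against control animals 2 and 3. Its calls can therefore hold part of the genotype difference and do not by themselves show another structure of the samples. At an adjusted p under 0.1 the real split gave 2120 genes and this one 15, and at an unadjusted p under 0.05 they gave 4154 and 1955. Of the gene lists the real split called 16, the only split with at least as many (1 of 10). The other splits called 8 to 15 lists, so that the number of called lists hardly tells the real split from other groupings.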
